A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

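RNA from the skin of 30-day-old rabbits (Oryctolagus cuniculus) was sequenced in 6 libraries, 3 labelled Prss53 knockout (made with CRISPR/Cas9) and 3 labelled wild type. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit. The submitters' processing notes name bcl2fastq 2.17.1.14 and cutadapt. The aligner, the transcript assembler, the program that called transcript events and the genome build are not given in the sources used here, so coordinates below are those of the authors' files with no build attached. Nothing states that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

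Each library has 1 table. Per the file headers, each row is a transcript event of an assembled locus (a first exon, a last exon, an exon included or skipped, an intron retained or spliced, or an alternative exon boundary, 20 event types in all), with the FPKM the authors computed and, for most loci, an Ensembl gene ID. FPKM, the unit of the deposited values, scales the fragments assigned to a transcript by its length and by the mapped fragments of the library. No row is at 0 and the lowest listed value is 0.000171, so an event or gene missing from a library is written here as not listed, and it entered the computations as 0. Such a missing row can be a failed assembly as well as an absent transcript. The tables hold no counts, so sequencing depth is unknown and no counting interval is given. The 6 tables hold 76612 events at 15280 loci.

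From these rows a gene value was computed. For each locus and library it was the largest of the summed first-exon events, the summed last-exon events and the highest single event. The first-exon and last-exon sums were equal within 0.1% at 66.4% to 69.8% of the loci that had both, depending on the library. Loci that share an Ensembl ID (447 IDs at more than 1 locus) were added together, and loci without an ID were kept as they are, which gave 14797 genes, 12276 of them with an Ensembl ID. Adding up the loci was decided after a first fit on single loci had been seen, because the 2 overlapping loci of 1 ID moved in opposite directions there. The count for single loci is among the alternatives. A gene spanning loci on both strands may mix 2 transcription units.

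The files do not pair Ensembl IDs with gene names. The RefSeq gene table supplied with them (38822 genes) has no Ensembl IDs in its cross-reference column, and 0 of the 12276 IDs matched. Gene names were therefore not assigned. Prss53 itself, the 38 gene lists and cell type markers fixed before the data were examined, and the count-based tests and alternatives foreseen for whole-number counts, were not analysed here. The rule for named genes fixed before the data were examined took, in each direction, the 12 genes with a symbol and the largest log2 fold change among those with an adjusted p under 0.05, a mean of at least 1 FPKM in 1 group and groups that do not overlap. It was applied with 2 Ensembl IDs in each direction in place of symbols. A further 10 genes in each direction were then taken by the same ranking from chromosome-anchored genes listed in all 6 libraries, and they are described by position. This change and the choice of genes listed in 1 genotype were made after the values were seen.

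Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and a mean-variance trend, genotype as the only term, two-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Chromosomes, with all unplaced scaffolds as 1 set, were tested as 23 gene sets with limma's camera at its preset correlation of 0.01.

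The analysis of single transcript elements was added after the files had been seen. For each skipped exon and each retained intron the FPKM of both forms was summed over the matching simple events. For genes with several first or last exons the FPKM of each was divided by the sum of that type at its locus. Elements with both forms together at 1 FPKM or more in every library were tested with limma on the share of FPKM, with 1 adjustment over all 4 kinds of element. Events of multiple exons or introns and events with inexact flanks entered only the count of listed events. Measures with 1 value per library were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

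Both tests were first run on simulated data that kept the means and spread of the real rows, with 200 rows changed. For gene levels (10809 genes), 31% of the changes of 1 log2 unit and 79% of those of 2 log2 units were recovered, and 5.17% of the calls were false. For exon inclusion (3358 exons), 43% of the share differences of 0.25 and 87% of those of 0.5 were recovered, and 5.11% of the calls were false. The simulated values were independent normal draws, with no missing rows, no bounds on shares and no library that stood apart. Among the real calls, 85 of the 114 elements had a form not listed in 1 genotype, so these rates need not carry over.

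Alternatives covered the scaling of libraries (equal medians, quantile normalization), the filter on low values, the pseudocount, a fold threshold, library quality weights, the replicate number as a block, the gene value, the unit of a gene, the scale and minimum level of the shares, and leaving out each library in turn. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib.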

Results

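Skin of 30-day-old rabbits was profiled by RNA sequencing in 3 Prss53 knockout and 3 wild-type libraries, to ask which transcripts differ in skin that lacks Prss53, a trypsin-like serine protease. The knockout libraries listed 46777, 47681 and 47183 transcript events and the wild-type libraries 46368, 48726 and 49081. Between 12237 and 12477 genes were listed per library, and 10835 of the 14797 genes were listed in all 6. Levels are FPKM as the authors deposited them, with no read counts, so depth is unknown. The gene names behind the Ensembl IDs are not paired with them in the files, so the level of Prss53 in each library was not analysed here and could not serve as a check of the labels.

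Across the 10809 genes tested, knockout replicate 3 stood apart from its group. Its log2(FPKM + 1) values correlated with those of knockout replicates 1 and 2 at 0.897 and 0.903, while these correlated with each other at 0.948 and the wild-type pairs lay between 0.949 and 0.953. These are Pearson correlations across genes, which are not independent replicates. In knockout replicate 3, 656 genes lay at least 2-fold below both other knockout libraries, against 130 and 102 in knockout replicates 1 and 2 and between 89 and 106 in the wild-type libraries.

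Knockout skin differed from wild-type skin in 102 genes, 59 higher and 43 lower (limma on log2(FPKM + 1), adjusted p under 0.05). In all 102 every knockout library lay on 1 side of every wild-type library. Among the 62 called genes listed in all 6 libraries, 38 were higher and 24 lower, with changes between 1.88-fold and 7.56-fold and a median of 2.8-fold on the log2(FPKM + 1) scale. When only genes listed in all 6 libraries were tested, 37 passed (24 higher, 13 lower), and 38 passed with a mean of at least 5 FPKM (24 and 14). Of all genes tested, 1749 had an unadjusted p under 0.05, where chance gives about 540, and 26.1% had groups that did not overlap, where chance gives 10%. The count and the balance of directions depended on the libraries used: more genes were lower than higher without knockout replicate 1 (17 higher, 44 lower), 2 (9 and 16) or 3 (31 and 46), and nearly all were higher without wild-type replicate 1 (8 and 0), 2 (9 and 2) or 3 (11 and 0). Part of this is built in by the filter. A called gene that reaches 1 FPKM in 1 genotype alone, as 41 of the 102 do, is not tested once a library of that genotype is left out. Among these genes, leaving out a knockout drops higher genes and leaving out a wild type drops lower ones. The count was 61 with a pseudocount of 0.1, and 220 with library quality weights, 111 of them higher and 109 lower.

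The gene on an unplaced scaffold from 953544 to 959027, plus strand, was the only 1 of the 102 to pass the threshold in all 6 fits that left out 1 library, and it was chosen for this after the values were seen. It had 61.3, 70.4 and 82.0 FPKM in the knockouts and 8.60, 8.70 and 8.64 FPKM in wild type (limma log2 fold change 2.89 ± 0.16 SE, adjusted p = 0.000537, at most 0.0188 in those fits). The other genes of this paragraph are on chromosomes and listed in all 6 libraries, and larger changes on unplaced scaffolds are left out. A gene on chromosome 13 from 39473515 to 39477527, made up of 2 overlapping loci on opposite strands, rose from 68.8 ± 19.6 to 602 ± 444 FPKM (SD, n = 3 per group), with 1115 FPKM in knockout replicate 3 and 355 and 337 FPKM in the other knockouts (limma log2 fold change 2.92 ± 0.48 SE, adjusted p = 0.0483). It passed in 1 of the 6 fits that left out 1 library, with an adjusted p of up to 0.212. Another gene on the same chromosome, from 39016888 to 39018876, rose from 2.30 ± 0.522 to 12.3 ± 5.18 FPKM (passed in 1 of the 6). On chromosome 2, the gene from 115119359 to 115166108 rose from 1.72 ± 0.984 to 16.4 ± 0.806 FPKM (limma log2 fold change 2.73 ± 0.25 SE, adjusted p = 0.00649, passed in 4 of the 6). On chromosome 5, the minus-strand gene from 27498985 to 27502979 rose from 7.40 ± 2.26 to 43.1 ± 3.71 FPKM (limma log2 fold change 2.43 ± 0.23 SE, adjusted p = 0.00761). It passed in 5 of the 6, with a largest adjusted p of 0.0541. The gene on chromosome 14 from 93169690 to 93172758 rose from 50.3 ± 4.16 to 205 ± 66.7 FPKM as measured by the largest of its event sums and passed in 3 of the 6, but its summed first-exon events alone gave a log2 change of -0.49. Other rises in this group were at 26902975 to 26915602 on chromosome 7 (7.37 to 31.7 FPKM), at 40930164 to 40946085 on chromosome 17 (5.43 to 20.1 FPKM), at 139870575 to 139877067 on chromosome 13 (3.52 to 12.7 FPKM), at 68595412 to 68603910 on chromosome 16 (0.243 to 3.46 FPKM) and at 102184773 to 102371489 on chromosome 1 (2.32 to 8.22 FPKM), which passed in 1, 1, 3, 0 and 2 fits, the chromosome 16 gene being tested in 3. The most abundant gene that rose was on chromosome 3 from 97143559 to 97147912, with 2108, 1837 and 1599 FPKM in the knockouts and 886, 804 and 869 FPKM in wild type. It was chosen after its values were seen and passed in 1 of the 6.

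Among genes listed in every library, the largest fall on the log2(FPKM + 1) scale was on chromosome 10, where the gene from 9173131 to 9180391 fell from 68.7 ± 11.0 to 11.8 ± 2.78 FPKM (SD, n = 3 per group; limma log2 fold change -2.45 ± 0.21 SE, adjusted p = 0.00580). It passed the threshold in 4 of the 6 fits that left out 1 library. A locus without an Ensembl ID on chromosome 1, from 148199825 to 148228576, fell from 15.1 ± 2.39 to 2.23 ± 1.09 FPKM (passed in 2 of the 6). The gene from 118061383 to 118077647 on chromosome 2 fell from 19.9 ± 1.26 to 3.38 ± 1.43 FPKM (limma log2 fold change -2.31 ± 0.25 SE, adjusted p = 0.0113, passed in 2 of the 6). With a pseudocount of 0.1 the log2 changes of these 3 were -2.54, -2.79 and -2.61, so their order depends on it. On chromosome 12, the gene from 122541187 to 122649124 fell from 39.7 ± 6.90 to 11.2 ± 1.72 FPKM (passed in 2 of the 6). On chromosome 7, 3 genes fell, at 28816332 to 28826521 (12.3 to 3.02 FPKM), 1421174 to 1528811 (10.3 to 3.11 FPKM) and 30350001 to 30452672 (10.3 to 3.67 FPKM), which passed in 1, 2 and 1 of the 6. The other falls in this group were at 126757194 to 126773666 on chromosome 13 (13.8 to 3.78 FPKM), 135730986 to 135939287 on chromosome 3 (15.8 to 4.48 FPKM) and 31526708 to 31554853 on chromosome 20 (4.34 to 1.03 FPKM), which passed in 2, 0 and 1 of the 6.

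**Figure D1:**
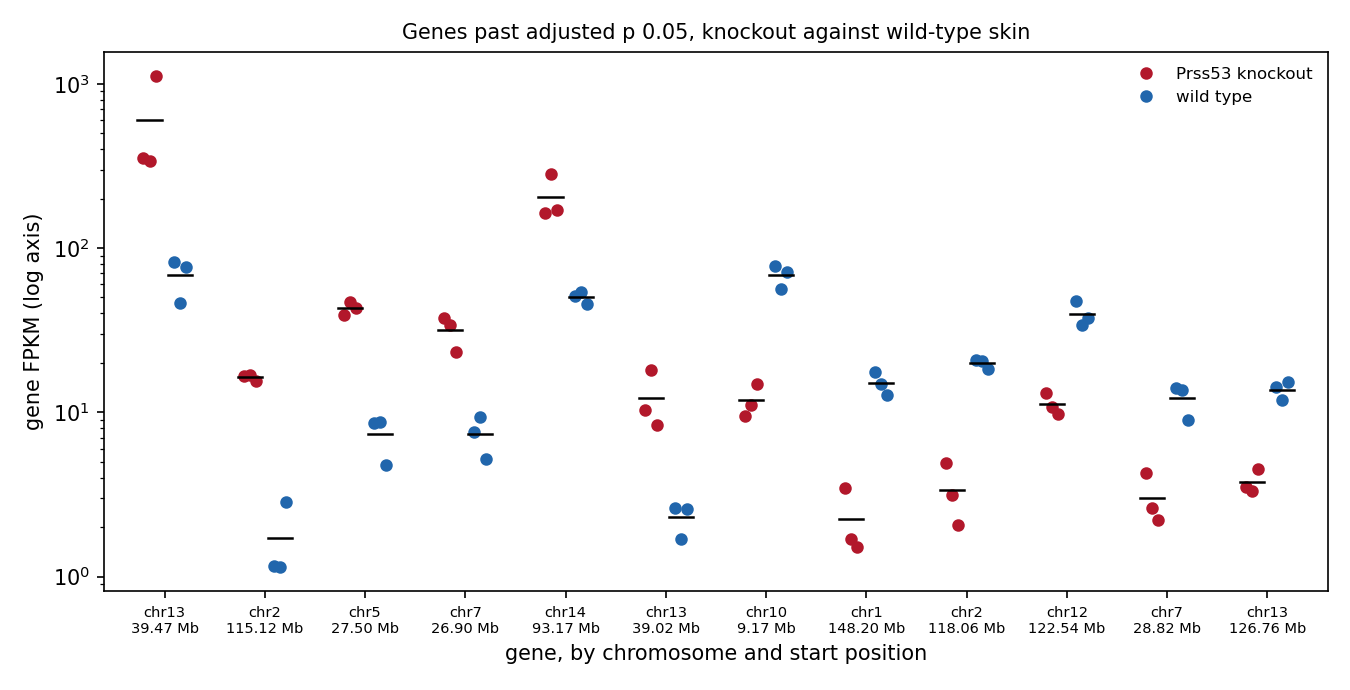
Gene FPKM on a log axis in each library for 6 genes that rose and 6 that fell in Prss53 knockout skin, by chromosome and start position. Points are libraries (3 per genotype) and lines are group means; in each gene shown the knockout libraries lie on 1 side of the wild-type libraries, as in all 102 genes past the threshold.

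Part of the difference consisted of genes listed in 1 genotype and missing from the other. Of the 102 genes, 15 were listed in the 3 knockout libraries and in no wild-type library, and 14 in the 3 wild-type libraries and in no knockout library. No fold change is given for these. Among them, ENSOCUG00000019629, on an unplaced scaffold, was listed at 8.18, 6.50 and 10.6 FPKM in the knockouts (limma adjusted p = 0.000945). A chromosome 12 locus without an Ensembl ID, from 62137536 to 62144723, was listed at 18.4, 20.5 and 19.3 FPKM in the knockouts. Listed in wild type alone were ENSOCUG00000029117, on the minus strand of the mitochondrial chromosome from 17135 to 17246, at 46.5, 33.6 and 21.6 FPKM (limma adjusted p = 0.000537), and ENSOCUG00000000709, on chromosome 9 from 78006317 to 78073905, at 13.9, 6.35 and 6.44 FPKM (limma adjusted p = 0.00617). An unplaced-scaffold locus without an Ensembl ID had 124, 91.0 and 81.4 FPKM in wild type, and a chromosome 12 locus from 122309799 to 122337136 had 11.2, 11.5 and 13.8 FPKM. ENSOCUG00000000357, on chromosome 1 from 19214404 to 19216096, was at 11.6, 12.2 and 18.6 FPKM in the knockouts and at 1.44 and 1.29 FPKM in wild-type replicates 1 and 2, and was not listed in wild-type replicate 3 (limma adjusted p = 0.0161). It passed in 2 of the 6 fits that left out 1 library. The genes named above as listed in 1 genotype passed in the 3 fits that could test them. Those fits leave out only libraries that do not list the gene, so they do not test its spread where it is listed. This does not hold for all such genes: of the 41 called genes that could be tested in only 3 fits, 21 passed in none.

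The same contrast was seen over all transcript events. The 3 knockout libraries shared 626 events that no wild-type library listed, and the wild-type libraries shared 794 that no knockout library listed. The other 18 sets of 3 libraries shared between 138 and 306 events in this way, with a median of 203. For events reaching 5 FPKM the numbers were 167 and 181, against at most 48 in any other set. Wild-type-only events exceeded knockout-only events most among retained or spliced introns (179 against 94), and less among exon inclusion or skipping (201 against 162), last exons (145 against 123), first exons (175 against 164) and exon boundaries (94 against 83); differences between these classes were not tested.

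**Figure D2:**
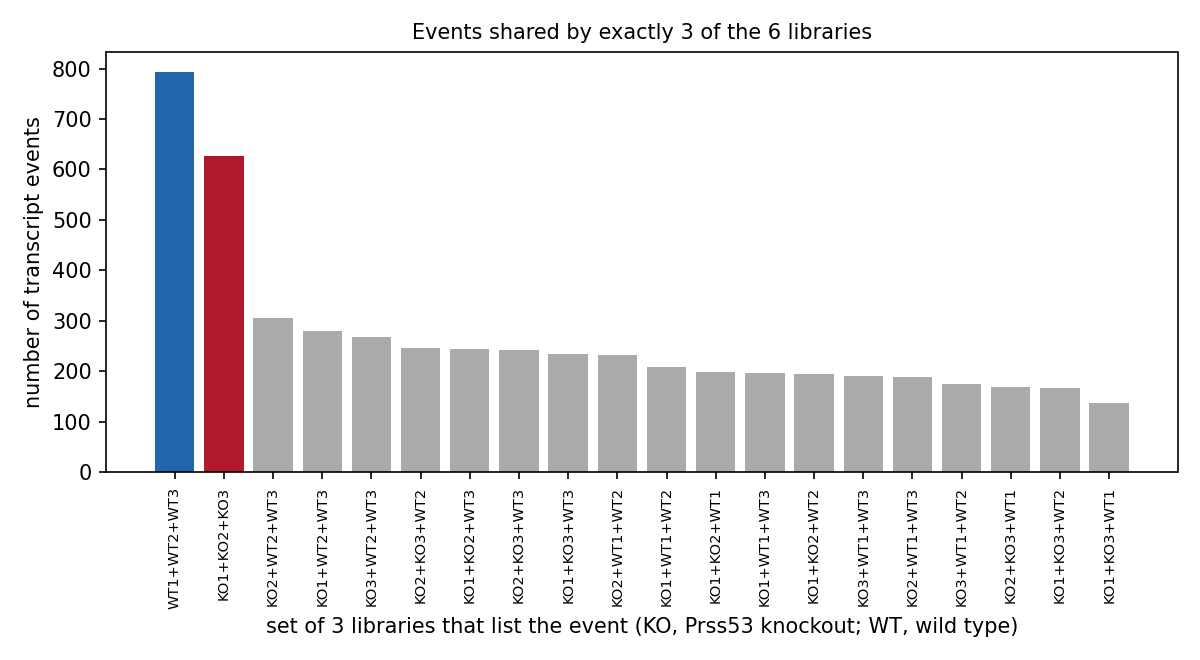
Number of transcript events listed in exactly 3 of the 6 libraries, for each of the 20 sets of 3. The wild-type set (794 events, blue) and the Prss53 knockout set (626 events, red) stand above the other 18 sets (grey), which reach at most 306.

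Transcript structure was then compared within genes, as the share of FPKM carried by each form. In 82 genes at least 1 element differed between knockout and wild type (114 of 16305 elements, limma on shares, adjusted p under 0.05). At an unadjusted p under 0.05 there were 1090, somewhat more than the share of 0.05 that chance gives. Elements are not independent, since alternative first or last exons of 1 locus enter as complementary shares. The 114 were 17 exons in 15 genes, 17 introns in 14 genes, 52 first exons in 37 genes and 28 last exons in 18 genes. In 85 of the 114 elements 1 form was not listed in any library of 1 genotype, so shares of 0% and 100% below mean that a form was not listed. The count was 46 genes without knockout replicate 2, 53 without knockout replicate 3, 47 without wild-type replicate 1 and 38 without wild-type replicate 2. It was 36 with a minimum of 5 FPKM. With the replicate number as a block no gene passed, and none of the 16 elements named by rule did. The labels state no pairing by that number.

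Among exons, an 81-base exon on chromosome 12 from 23920946 to 23921026 was included in 94.1% ± 1.36 of the FPKM in knockout and 37.8% ± 0.593 in wild type (SD, n = 3 per group; limma adjusted p = 0.00262). Both forms of this exon together had 1.68 to 7.39 FPKM. A 63-base exon on chromosome 8 from 97471216 to 97471278 was at 0% in each knockout and at 53.9%, 55.6% and 48.1% in wild type, with 7.52 to 9.27 FPKM of both forms together. A 750-base exon on chromosome 15 from 61855574 to 61856323 was at 0% in each knockout and at 75.2%, 73.0% and 72.2% in wild type, at a level of 1.42 to 4.13 FPKM. An exon of 972 bases on chromosome 19 from 46322926 to 46323897 was at 100% in each knockout and 53.8% ± 3.97 in wild type, at a level of 1.11 to 4.48 FPKM.

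Among introns, 4 had a higher retained share in knockout and 13 a lower one. On chromosome 13 the intron between exon ends at 74454605 and 74456668 was retained in 60.3%, 76.9% and 61.4% of the FPKM in wild type and in 0% in each knockout. Introns between 125267843 and 125270001 on chromosome 2 and between 150528388 and 150532643 on chromosome 7 were retained at 44.6% ± 2.27 and 40.4% ± 3.84 in wild type and at 0% in the knockouts. Levels of both forms together were 1.45 to 9.82 FPKM (chromosome 2) and 2.83 to 7.33 FPKM (chromosome 7). On chromosome 4 the intron between 4897914 and 4900165 went the other way, with 60.0%, 75.3% and 68.2% in the knockouts and 0% in wild type. Its level was 1.00 to 2.77 FPKM, near the minimum of the test. Averaged over all 2126 introns tested, the retained share did not separate the genotypes: it was 15.9% ± 0.714 in knockout and 17.9% ± 2.99 in wild type (SD, n = 3 per group; exact permutation test, two-sided, p = 0.4).

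**Figure D3:**
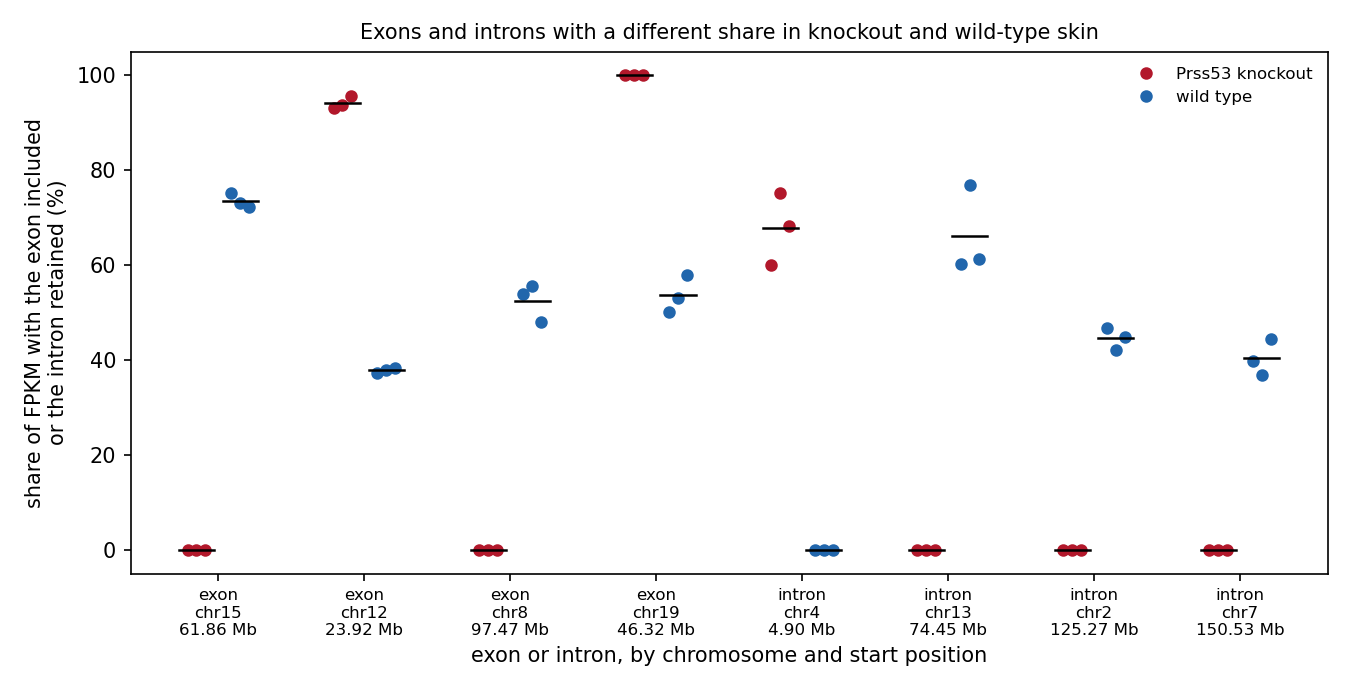
Share of FPKM (in %) with the exon included or the intron retained in each library, for 4 exons and 4 introns past the threshold. Points are libraries (3 per genotype) and lines are group means; for example, the chromosome 12 exon has a mean of 94.1% in Prss53 knockout and 37.8% in wild type.

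First and last exons changed too, some of them in well-expressed genes. On chromosome 15 the first exon from 92289123 to 92289266 carried 100% of the first-exon FPKM in each knockout and 5.93% ± 1.27 in wild type, where the first exon from 92267696 to 92268129 carried 95.4%, 93.9% and 82.6% (limma adjusted p = 0.000405 and 0.00262). The summed level of this gene's first exons lay between 103 and 264 FPKM. On chromosome 9 the first exon from 58821159 to 58821350 was at 0% in each knockout and 58.0% ± 2.85 in wild type, at 121 to 223 FPKM. On chromosome 3 the 55-base first exon from 16874170 to 16874224 was at 90.4%, 73.9% and 100% in the knockouts and at 0% in wild type. On chromosome 12 the one from 145240008 to 145240149 was at 0% in the knockouts and 44.2% ± 3.76 in wild type, at 2.56 to 6.19 FPKM. Last exons at 25436680 to 25440413 on chromosome 19 and at 9308593 to 9311221 on chromosome 21 were at 100% in each knockout and 0% in each wild-type library. Levels were low, with 2.43 to 3.41 FPKM (chromosome 19) and 1.18 to 2.53 FPKM (chromosome 21) over all last exons of the locus. The chromosome 21 gene used a last exon with the same outer end, from 9308593 to 9310625, in wild type. At 52333723 to 52338736 on chromosome 19 the share was 100% in each knockout and 65.6% ± 0.375 in wild type. There too the other last exon, from 52333723 to 52341282, has the same outer end. A changed share of a last exon therefore need not be a change of the transcript end. The chromosome 13 gene at 39473515 also had a last exon, from 39474282 to 39475241, at 0% in the knockouts and at 100%, 100% and 82.3% in wild type.

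The called genes were spread over the chromosomes. Chromosome 13 held 7 genes that rose and 1 that fell, unplaced scaffolds held 26 and 13, and chromosomes 18, 19 and 21 held none. Chromosome 13 also had the most tested genes of any chromosome (804 of 10809), and its rises include the overlapping loci at 32016935 and 32060277. Unplaced scaffolds carried 38.2% of the called and 27.3% of the tested genes (Fisher's exact test, two-sided, p = 0.0184). Genes without an Ensembl ID were 22.5% of the called and 6.75% of the tested genes (Fisher's exact test, two-sided, p = 2.16e-07). Both tests count genes as independent, although all were measured in the same libraries. Most called genes without an ID were not listed in every library, and the missing rows entered as 0, while most of those with an ID were listed in every library. How far missing rows account for the difference was not tested. None of the 23 sets made of a chromosome or of all unplaced scaffolds shifted as a whole (limma camera, 0 at an adjusted p under 0.05, 3 at an unadjusted p under 0.05, and 0 at either with an estimated correlation). The median log2 fold change was 0.01 for unplaced scaffolds, -0.18 for chromosome 7 and -0.19 for chromosome X. Unplaced scaffolds passed when knockout replicate 1 was left out (adjusted p = 0.0177), and unplaced scaffolds and chromosome 7 passed when knockout replicate 2 was left out (0.0150 and 0.0324). Knockout replicate 3 lay above the other knockouts by a median of 0.28 log2 units on unplaced scaffolds and below them on chromosome 7 (-0.18).

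Of 40 counts, levels and shares with 1 value per library, 7 separated the genotypes (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows), where chance gives about 4, so none is taken as a difference. Among these 7, the 100 highest genes held 35.1%, 37.7% and 36.9% of the summed gene FPKM in the knockouts and 32.9%, 33.4% and 31.7% in wild type, 36.6% ± 1.36 against 32.7% ± 0.861 (SD, n = 3 per group; exact permutation test, two-sided, p = 0.1). The 10 highest held 12.7% ± 0.779 and 10.8% ± 0.385 (SD, n = 3 per group; exact permutation test, p = 0.1). The median over listed genes was 5.86 ± 0.203 FPKM in knockout and 6.31 ± 0.241 FPKM in wild type (SD, n = 3 per group; exact permutation test, p = 0.1).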

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

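The alternatives on single loci, on the gene value, on genes listed in all 6 libraries, on shares, events, chromosomes and library averages were chosen after the data were seen. The count of 102 genes was 103 with equal medians (69 higher, 34 lower) and 110 with quantile normalization (72 and 38), with 93 and 94 of the same genes. Both moved the median log2 change from -0.07 to 0.02. The count was 112 for single loci, 38 with a mean of at least 5 FPKM, 61 with a pseudocount of 0.1, 220 with library quality weights (all 102 among them) and 37 for genes listed in all 6 libraries. The 5 FPKM minimum and the listing in all 6 libraries leave fewer genes to test. The causes of the other differences were not tested. Leaving out 1 library gave 8 to 77 genes. A gene that reaches 1 FPKM in the 3 libraries of 1 genotype alone cannot pass the filter once 1 of these is left out, which concerns 41 of the 102 (29 of them not listed in the other genotype). All 102 kept their sign in every such fit that tested them, 1 passed in all 6, and 37 passed in none (21 of the 41 and 16 of the other 61). For the genes named by rule, 49 of 132 values without 1 library stayed past the threshold and 83 did not. Under the other settings 250 of 278 stayed past it, 27 did not, and 1 reversed, the chromosome 14 gene at 93169690 (-0.49 with summed first-exon events).

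Genes with a differing transcript element numbered 82 in the main test, 36 with at least 5 FPKM, 106 with log2 ratios, 77 with arcsine shares, 82 with adjustment within each kind, and 38 to 65 without 1 library. Events listed in 1 genotype numbered 1420, 348 with at least 5 FPKM, and 2301 to 2624 without 1 library, where fewer libraries must list or lack an event. Of the 23 chromosome sets, 0 to 2 passed without 1 library. The mean intron retention difference lay between -3.59 and -0.64 percentage points and the top-100 share difference between 3.31 and 4.63, without 1 library. Replicate numbers are shared between the genotypes. Deviations of same-numbered libraries correlated at -0.00499, 0.144 and 0.0471, which gives little sign of pairing. With so few libraries pairing is not excluded, and the labels state none. With the replicate number as a block, 81 genes passed (66 of the 102), and 0 genes with a differing element did (limma, 1009 elements at an unadjusted p under 0.05). Depth is unknown, so it sets no stated limit here. Alternatives for counts, for Prss53 and for the gene lists were not run.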

Other observations

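Of the tests in this part, the searches for a gene within 5000 bases, a span trend and a chromosome trend were chosen before their results were seen. The others were chosen after. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each case 1 of the 10 splits, the real one, gave as many: 102 genes against at most 3 in another split, 82 genes with a differing transcript element against at most 4, and 1420 genotype-specific events against at most 466.

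Of the 82 genes with a differing transcript element, 2 were also among the genes called by level, where 0.366 would be expected by chance among the 5372 genes in both tests. The wild-type libraries varied widely in intron retention. The retained form was listed for 39.8%, 55.0% and 62.7% of the 2126 introns tested in wild-type replicates 1, 2 and 3 and for 48.7%, 43.4% and 45.6% in the knockouts. Exon inclusion was more even, with mean shares of 50.9% to 51.7% over the 3358 exons.

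In 29 called genes the transcript was listed in every library of 1 genotype and in none of the other, with group means up to 98.9 FPKM. Of the 29, 18 have another gene within 5000 bases, and 0 of the 29 have one that changed the other way at an unadjusted p under 0.05 (exact 95% interval over all 29, 0% to 11.9%). For these 18 this argues against a shift of FPKM to a locus of similar level within 5000 bases. The interval counts all 29, so it is narrower than 1 over the 18 alone would be. The rest have no such neighbour and could not show a shift. A shift into a more abundant neighbour could also pass unseen, as the median levels were 3.13 FPKM (listed in knockout) and 5.71 FPKM (listed in wild type). Random loss near the detection limit is argued against as the whole cause, since among genes with at least 1 FPKM in each library that lists them, as the gene test requires, 17 were listed in the knockouts alone and 15 in wild type alone, against at most 7 in any other set of 3 libraries. This depends on the minimum, which was settled after others had been tried. Of 11 minima on the lowest or highest value, the knockout set stood above the highest other set by over 2 times its square root in 6. The wild-type set did so in 5 (with a highest value of at least 2 FPKM, 21 and 14 against 12). Neither did so at 5 or 10 FPKM, where few genes remained (with a lowest value of at least 5 FPKM, 2 and 6 against 3). Loss of some of the genes is therefore not excluded. Also open are an effect of the genotype, a difference in parentage between the groups, or a sequence difference from the reference that stopped assembly. None of these was tested, as the labels give no parentage.

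Knockout replicate 3 had 656 genes at least 2-fold below both other knockouts, and in 99.1% of them it was also below the wild-type mean. The choice of these genes largely fixes that share, since the other knockouts lay near wild type in them (median log2 difference -0.137). The number of listed genes argues against a smaller number of detected genes (12387 listed, within the 12237 to 12477 of the other libraries). At 1 FPKM or more this library did have the fewest genes, 10600 against 10625 to 10736 in the others. Both a span trend and a scaffold trend were present in this library. Its deviations correlated with genomic span (Spearman -0.255). The low genes had a median span of 41.3 kb, against 28.1 kb for all genes, and 10.2% were on unplaced scaffolds, against 27.3% of tested genes. Centring removes only the mean shift of each bin. It left 707 low genes within span bins (at most 117 in another library) and 688 within chromosomes (at most 116). These counts argue against either trend as the whole cause, but not as a part of it. A wild-type library under a knockout label is argued against as well: this library listed 49.4% of the 1266 events found in both other knockouts and no wild type, and 29.1% of the 1120 events found in all wild types and neither other knockout. Another cell composition, RNA quality or hair cycle stage of that sample stays open and was not tested, since marker genes are not named in the files.

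A hypothesis was that called genes lie in linked regions, as they may if the groups differ in inherited segments around a target. Among 63 called genes on chromosomes, 5 neighbouring pairs lay under 1 Mb apart, against a median of 3 and a 95th percentile of 7 in 10000 random gene sets, and 26.7% of the random sets had as many. This neither shows nor excludes such regions. Of the 5 pairs, 4 moved the same way, such as the chromosome 13 genes at 39016888 and 39473515, which both rose. Another of these 4, on chromosome 13 at 32016935 and 32060277, consists of overlapping loci on the same strand, so it is not a pair of separate neighbours. The pair that moved in opposite ways was the chromosome 4 genes at 36165215 (listed in knockout alone) and 36509746 (listed in wild type alone).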
